A study of Mus musculus with 18 samples.

How the data were processed

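RNA from embryonic spinal cords of Aldh1l1-GFP transgenic mice was measured on 18 microarrays. Per the labels' protocols, cords on a Swiss-Webster background were dissociated with papain and flow sorted, RNA was extracted with TRIzol, treated with DNase and cleaned on a column, and it was amplified and labelled with biotin before hybridisation. The titles call the comparison samples all live sorted cells and the cell type label calls them whole spinal cord, while the treatment text shared by every sample speaks of GFP-negative cells. They were taken here as all live cells, following the titles. Such a sort still holds the GFP cells, so a ratio of GFP cells to all live cells understates the contrast with GFP-negative cells.

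The main values are the authors' deposited log2 expression values, per probe set, for 35556 probe sets on each array. Per the submitters' processing notes the tools oligo, RMA and limma were used, with the build mm9 listed, and their versions are not given in the sources used here. The deposited comparison tables give a linear fold (GFP over whole), a moderated t score, a p-value and an adjusted p-value for each listed gene at E13.5 and E14.5, and the fold and adjusted p-value at the late age. The authors' deposited coexpression tables give a score per gene and module, the correlation of the gene with the profile of the module (kME), with its p-value. Each of the E13.5 and E14.5 comparison tables also holds 3 columns of values headed for GFP cells at E14.5 whose letters could not be matched to sample labels. These columns, 3 in each of the 2 tables, were not used, and neither were the 2 second sheets that copy the first.

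The value table names its probe sets by number only. Names were taken from the deposited tables by matching values: all 1875 genes of the E13.5 table and all 552 of the E14.5 table matched a probe set within 1e-08, and the module table was matched through the kME values, which were recomputed from the 17 assigned arrays. All 23890 genes of the module table matched within 1e-08, of which 135 matched more than 1 probe set. In this way 23874 probe sets received a name, and 1921 of the 1948 probe sets named by both tables had the same name in each. Symbols were brought up to date with a RefSeq gene table (assembly GRCm38.p6, used for names only): 17253 names were current, 3331 were older symbols, 3104 were not in that table and 202 were broken by spreadsheet conversion. No coordinates are given, because the builds differ. Where a gene had several probe sets (37 genes), the one with the highest mean over the assigned arrays was used, which left 23850 genes.

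Groups came from the sample labels. The late group joins 2 arrays of E17.5 with 1 of E18.5 in each sort, because the replicate numbering of the titles runs through both ages. The array that its title calls mislabeled was left unassigned and entered no comparison. All 17 assigned arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit on 6 group means, contrasts.fit, eBayes; 11 residual and 5.42 prior degrees of freedom), and 8 contrasts were tested with Benjamini-Hochberg adjustment over the 23850 genes and a threshold of 0.05. Values after ± are limma's standard errors on the log2 scale, from 1 spread per gene shared by all groups. No batch or scan date is given in the labels. Arrays carry no read depth, and their number limits the precision. In a limma test on simulated data with the real group sizes, 98.5% of genes changed by a log2 of 1 were recovered for GFP against whole at E13.5, 92.5% at E14.5, 95.5% at the late age, 97% for GFP late against E13.5, 88.1% for GFP E14.5 against E13.5, 95.5% for GFP late against E14.5, 95.5% for whole late against E13.5 and 92.5% for the interaction. At a log2 of 0.5 the range was 29.9% for the interaction to 67.2% for GFP against whole at E13.5. In each contrast 67 of 23850 genes were changed at either size, with noise drawn independently for each gene. The adjustment depends on how many genes change, so recovery in the real data can differ.

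There were 21 gene lists, and they were tested with limma's camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. An estimated correlation and fry were alternatives. A small p from fry says that the genes of a list move, on balance, in the same direction, without comparing them with other genes. Each list was also counted gene by gene, over all genes tested and adjusted over the list alone. Members not measured under a usable name were Tcf7l1, Rbfox3, Hbb-bt, Ahsp, Drgx and Hspa1b. The design, the tests, the lists, the alternatives and the rule for the genes named were chosen before the data were examined. That rule took, for each contrast, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap (a condition that chance meets for 10% of genes with 3 arrays against 3 and 20% with 3 against 2; it was not applied to the interaction), leaving out unnamed, predicted and near-identical family genes. It also took up to 4 members of each list with the smallest adjusted p, the 4 members of each module with the highest kME, and always Aldh1l1, Sox9, Nfe2l1, Nfia, Nfib, Gfap, Aqp4, Slc1a3, Fabp7, Olig2, Apcdd1, Mmd2 and Zcchc24. The globins stayed among the names; the probe sets of Hba-a1 and Hba-a2 belong to near-identical genes and cannot be told apart with certainty.

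The alternatives were the mean of a gene's probe sets, leaving out genes under the 40th percentile of mean value, quantile normalization of the 17 arrays, shifting each array to a common median, eBayes with a trend and robust variances, array weights, only the groups of a comparison in the fit, the replicate number as a block, leaving out each array in turn, a minimum log2 change of 1, and leaving out both E18.5 arrays. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.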

Results

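Expression was profiled in spinal cord cells of mouse embryos that carry the Aldh1l1-GFP transgene, in which green fluorescent protein follows the astrocyte enzyme Aldh1l1, across the ages at which radial glia give way to astrocytes. At each age, sorted GFP-positive cells (GFP cells) were set against all live cells sorted from the cord (whole). The GFP cells had 3 arrays at E13.5, 2 at E14.5 and 3 at the late age (E17.5 for 2 of them and E18.5 for 1). Whole had 3 arrays at each age, with the same make-up at the late age. The labels call the arrays biological replicates without naming litters or animals, so p-values measure the spread between these samples. Arrays of 1 group correlated with each other at 0.985 to 0.993 over all genes. In a principal component analysis of the 17 arrays, PC1 (44.5% of the variance) placed the GFP cells of each age above the whole samples of that age. PC2 (20.9%) placed the late samples above the E13.5 samples within each sort.

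The comparison of GFP cells with all live cells asks which transcripts belong to the Aldh1l1 lineage at each age. At E13.5 the GFP cells held more of astrocyte and radial glial transcripts and less of neuronal, blood and connective tissue transcripts (n = 3 against 3). Aldh1l1 itself, whose promoter drives the transgene, was 4.55-fold higher (2.19 ± 0.12 log2). Among the largest rises were Adamts3, a procollagen protease (2.66 ± 0.35), Gabrg1, a GABA receptor subunit (2.47 ± 0.11), and the peptide transporter Slc15a2 (2.43 ± 0.12). The glycolytic enzyme Aldoc (2.28 ± 0.13), the GABA transporter Slc6a11 (2.27 ± 0.18) and the metalloproteinase inhibitor Timp4 (2.30 ± 0.19) followed. Among the largest falls were the globins Hbb-y (-6.35 ± 0.27), Hbb-b1 (-5.52 ± 0.25) and Hba-a1 (-4.57 ± 0.13), the pericyte gene Rgs5 (-3.19 ± 0.26) and Mab21l2 (-3.01 ± 0.11). In all, 4557 genes passed the threshold, 2647 higher and 1910 lower in GFP cells, of which 323 and 266 differed at least by a log2 of 1. The share higher was 58.1%, against 67.5% with median shifting and 51.3% with quantile normalization.

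Of the 30 astrocyte genes 19 were higher and 2 lower at E13.5, the glutamate transporter Slc1a3 by 1.87 ± 0.07, Sparcl1 by 1.53 ± 0.07 and Ndrg2 by 1.84 ± 0.10. Of 20 radial glial and progenitor genes 14 were higher (Ptprz1 1.65 ± 0.12, Nes 1.24 ± 0.11, Sox2 0.94 ± 0.09). So were 15 of 19 gliogenic transcription factors (Id3 1.79 ± 0.14, Rfx4 1.44 ± 0.13, Nfia 1.10 ± 0.10) and 10 of 18 Notch pathway genes (Hey2 1.36 ± 0.15, Notch2 1.14 ± 0.12). The secreted and matrix proteins of astrocytes had 14 of 23 higher and 1 lower (Timp3 1.82 ± 0.12), and cholesterol synthesis had 9 of 20 higher (Idi1 1.26 ± 0.16). Mitosis had 19 of 24 higher (Ccnb1 1.12 ± 0.18, Cdk1 0.90 ± 0.12), or 23 adjusted over the list alone. DNA replication had 8 of 24 higher (Mcm6 0.75 ± 0.13) and proteasome subunits 8 of 31 (Psmd4 0.39 ± 0.08), but their calls were lost with adjusted p = 0.116 and 0.0812 with an estimated correlation. Dorsoventral patterning genes had 9 of 20 higher (Slit1 0.95 ± 0.08, Pax3 0.84 ± 0.10). Every measured pan-neuronal gene, 23 of 23, was lower (Ina -1.96 ± 0.15, Syt1 -1.91 ± 0.15). Also lower were 14 of 23 spinal neuron identity genes (Slc17a6 -2.23 ± 0.14, Lhx1 -1.59 ± 0.10), 10 of 14 erythroid genes, and 11 of 16 meningeal fibroblast genes, with 1 higher (Postn -2.48 ± 0.13). Camera's adjusted p for these lists lay between 9.56e-25 for pan-neuronal and 7.56e-05 for DNA replication.

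Markers of the other cells of the cord moved less evenly at E13.5. Of 18 microglia and macrophage genes 12 were lower (Mrc1 -2.53 ± 0.20, Ctss -1.75 ± 0.13; adjusted p = 9.28e-10), with adjusted p = 0.0733 with an estimated correlation. Of 18 endothelial genes 2 were lower and 1 higher (Cdh5 -0.53 ± 0.11; adjusted p = 0.0391, and 0.171 with an estimated correlation). Of 13 Schwann cell and ganglion genes 3 were lower (Scn9a -2.26 ± 0.29; adjusted p = 0.0189, and 0.0966 with an estimated correlation). Quantile normalization ended both calls, with adjusted p = 0.179 for endothelial and 0.0594 for Schwann cell genes. Mural genes (3 lower, 2 higher of 14, adjusted p = 0.0595) and oligodendrocyte lineage genes (3 higher, 1 lower of 20, adjusted p = 0.937) did not pass as lists. Neither did ependymal genes (1 higher, 1 lower of 16, adjusted p = 0.347) and immediate early genes (3 higher of 19, adjusted p = 0.775). The ependymal and immediate early medians (-0.02 and -0.07) had the opposite sign to their tests. For the other lists at this age, counts adjusted over the list alone differed by at most 4 from those given.

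At E14.5 the GFP cells (n = 2 against 3) again held more glial transcripts. Ttpa, the alpha-tocopherol transfer protein, was higher by 2.41 ± 0.17, the bicarbonate transporter Slc4a4 by 2.29 ± 0.15, the matrix glycoprotein Tnc by 2.33 ± 0.22 and Aldh1l1 by 1.80 ± 0.14. Hbb-y was lower by -6.49 ± 0.31, Rgs5 by -4.14 ± 0.29, the proteoglycan Spock3 by -3.25 ± 0.17 and the neuropeptide gene Tac1 by -2.87 ± 0.24. The threshold was passed by 4419 genes, 2458 higher and 1961 lower, and by 882 of them with a log2 change of at least 1. The share higher was 55.6%, against 63.2% with median shifting and 52.1% with quantile normalization. Astrocyte genes were higher for 20 of 30 (21 adjusted over the list alone), radial glial genes for 14 of 20 (Ednrb 1.71 ± 0.12) and gliogenic factors for 13 of 19 (Id3 1.78 ± 0.16). Notch genes were higher for 10 of 18 (Hey1 1.24 ± 0.11) and secreted and matrix proteins for 15 of 23 with 1 lower (Bcan 1.45 ± 0.10). Cholesterol synthesis was higher for 14 of 20 genes, or 17 adjusted over the list alone (Msmo1 1.22 ± 0.13, Nsdhl 0.97 ± 0.11). Pan-neuronal genes were lower for 22 of 23 (Syt1 -2.58 ± 0.17) and spinal neuron identity genes for 12 of 23 (Slc17a6 -2.25 ± 0.16). So were erythroid genes for 9 of 14, and meningeal fibroblast genes for 7 of 16 with 1 higher (Postn -1.74 ± 0.14).

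Several lists at E14.5 passed camera with the preset correlation but not with an estimated one. All of them passed fry, with adjusted p from 5.84e-05 for microglia to 0.0377 for proteasome subunits. Mitosis had 14 of 24 higher (Top2a 0.96 ± 0.15; adjusted p = 0.115 with an estimated correlation) and DNA replication 7 of 24 (Pcna 0.63 ± 0.10; adjusted p = 0.116 with it). Dorsoventral patterning had 8 higher with 1 lower of 20 (Pax3 1.03 ± 0.11; adjusted p = 0.0633 with an estimated correlation) and ependymal genes 6 with 1 lower of 16 (Mia 1.72 ± 0.14; adjusted p = 0.0963 with it). Microglia had 15 of 18 lower (Ctss -2.44 ± 0.15; adjusted p = 0.0612 with an estimated correlation) and endothelial genes 2 of 18 (Cdh5 -0.65 ± 0.13; adjusted p = 0.117 with it). Proteasome subunits had 2 of 31 higher and 0 adjusted over the list alone (median 0.10; adjusted p = 0.321 with an estimated correlation). Quantile normalization ended the proteasome and endothelial calls (adjusted p = 0.798 and 0.084). Oligodendrocyte lineage (2 higher, 3 lower, adjusted p = 0.169) and mural genes (2 higher, 4 lower, adjusted p = 0.12) did not pass as lists. Schwann cell (1 higher, 1 lower, adjusted p = 0.0562) and immediate early genes (2 higher, adjusted p = 0.379) did not either. The other counts at E14.5 differed by at most 5 when adjusted over the list alone.

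At the late age the GFP cells (n = 3 against 3) held less of microglial, vascular and globin transcripts and more of several astrocyte transcripts. Of 2214 genes past the threshold 1098 were higher and 1116 lower (49.6% higher, 58.1% without dim genes and 41.1% with quantile normalization). A log2 change of at least 1 was seen in 18 higher and 290 lower genes. The GFP cells within whole limit how large a rise can be at every age, and 323 genes rose that much at E13.5. The limit can account for the late count only if the share of GFP cells grew, which is taken up below. The macrophage receptor C3ar1 was lower by -4.11 ± 0.22, the lysosomal protease Ctss by -3.73 ± 0.13, the signalling adaptor Tyrobp by -3.58 ± 0.16 and Fcrls by -3.22 ± 0.29. Hbb-b1 stood at -5.29 ± 0.25 and Rgs5 at -3.89 ± 0.26. The largest rises included Ttpa (1.28 ± 0.16), the melanocortin receptor Mc5r (1.26 ± 0.15), carbonic anhydrase Car2 (1.19 ± 0.15), the astrocyte filament gene Gfap (1.16 ± 0.14) and Emp2 (1.11 ± 0.16). Calr4 was also higher (1.34 ± 0.29), but not without the E18.5 arrays (1.14, adjusted p = 0.07). With only these 2 groups in the fit, the count fell to 1020.

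Of the astrocyte genes 22 of 30 were higher at the late age, or 26 adjusted over the list alone (the gap junction gene Gja1 0.93 ± 0.09, the amino acid transporter Slc7a10 0.82 ± 0.10). Gliogenic factors were higher for 10 of 19, or 13 adjusted over the list alone (Id3 0.89 ± 0.14, Klf15 0.52 ± 0.09). Secreted and matrix proteins were higher for 6 of 23, or 13 adjusted over the list alone (Ncan 0.74 ± 0.09), and cholesterol synthesis for 5 of 20, or 11 adjusted over the list alone (Msmo1 0.55 ± 0.11). The microglia list was lower for 17 of 18 genes (median -1.65; Ly86 -3.22 ± 0.11) and the oligodendrocyte lineage for 14 of 20 (the precursor receptor Pdgfra -3.14 ± 0.14, Bcas1 -1.96 ± 0.16, Gpr17 -1.93 ± 0.13). Endothelial genes were lower for 12 of 18 (Slco1c1 -2.21 ± 0.12, Kdr -1.52 ± 0.10) and mural genes for 7 of 14 (Higd1b -2.20 ± 0.11). Pan-neuronal genes were lower for 19 of 23 (Dcx -2.07 ± 0.11), spinal neuron identity genes for 6 of 23 (Slc17a6 -1.51 ± 0.14) and erythroid genes for 4 of 14. Radial glial genes were higher for 5 of 20 (Ednrb 0.56 ± 0.11; adjusted p = 0.0563 with an estimated correlation) and Notch genes for 4 of 18 (Hey2 0.97 ± 0.15; adjusted p = 0.189 with it). Dorsoventral patterning genes were higher for 3 of 20, with 1 lower (Slit1 0.64 ± 0.08; adjusted p = 0.219 with an estimated correlation), and proteasome subunits for 3 of 31 (median 0.13; adjusted p = 0.183 with it). The ependymal list had 1 higher and 2 lower of 16 (adjusted p = 0.182 with an estimated correlation) and the meningeal list 1 lower of 16 (Postn -0.84 ± 0.13; adjusted p = 0.204 with it). Neither list passed fry (adjusted p = 0.0679 and 0.0724). No mitosis gene passed, 0 of 24 in limma (adjusted p of the list 0.969). Without the E18.5 arrays the list did pass (adjusted p = 0.0403), as did DNA replication (0.0053), which had 1 of 24 higher and adjusted p = 0.164 with them. Schwann cell (2 lower, adjusted p = 0.36) and immediate early genes (2 lower, adjusted p = 0.453) did not pass, and their medians (0.04 and 0.06) had the opposite sign to their tests. At the late age the other counts differed by at most 5 when adjusted over the list alone.

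**Figure D1:**
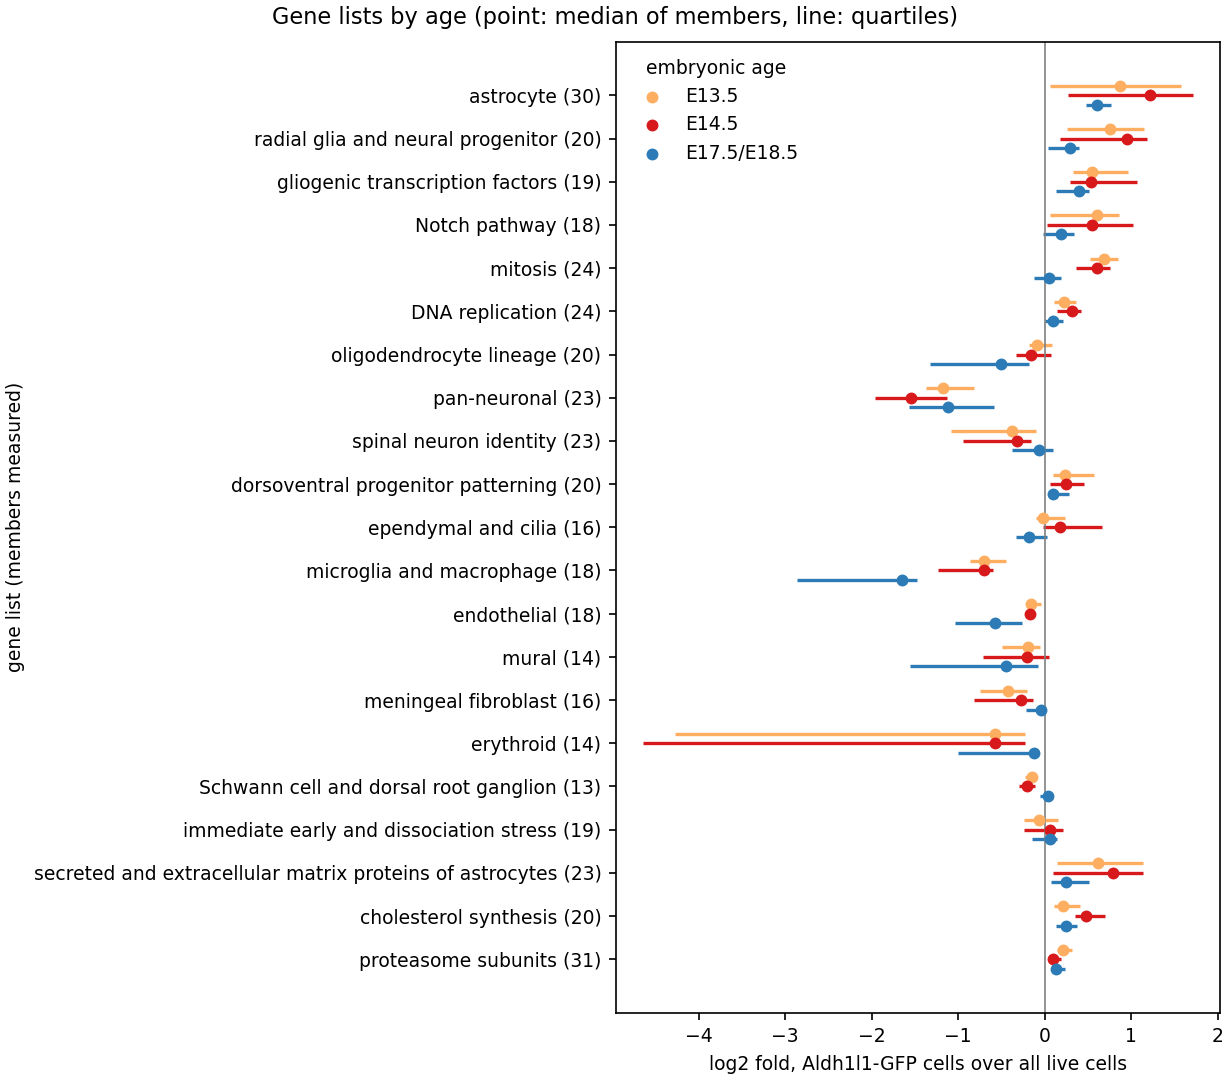
Median (points) and quartiles (lines) of the log2 fold of GFP cells over all live cells for the members of each gene list, with the number measured in brackets, at E13.5, E14.5 and the late age (E17.5 and E18.5). The microglia median lay at -0.70, -0.71 and -1.65, the astrocyte median at 0.87, 1.21 and 0.61, and the mitosis median at 0.68, 0.60 and 0.05.

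Calls were shared between the ages, whose arrays are separate but whose tests use the same estimate of spread per gene. A gene with a small spread passes more easily at every age, so numbers for independent lists are only a reference. Of the genes higher in GFP cells at E13.5, 1799 were also higher at E14.5, where independent lists of those sizes would share 273, and 699 were also higher at the late age (122 from independent lists). For lower genes the overlaps were 1220 (157 from independent lists) and 587 (89.4). Between E14.5 and the late age 729 higher and 673 lower genes were shared (113 and 91.8 from independent lists).

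Slc1a3 was higher in GFP cells at all ages, by 1.87 ± 0.07, 1.84 ± 0.08 and 0.66 ± 0.07. So was the membrane protein gene Mmd2, by 1.13 ± 0.09, 1.52 ± 0.10 and 1.00 ± 0.09. The gliogenic transcription factor Nfia was higher by 1.10 ± 0.10, 1.00 ± 0.11 and 0.56 ± 0.10. Sox9, which specifies glia, was higher by 0.98 ± 0.12 and 1.12 ± 0.14, and by 0.47 ± 0.12 at the late age. The late call ended with quantile normalization (0.36, adjusted p = 0.0718) and without GFP replicate 1 or 2 or whole replicate 1 or 3 (adjusted p = 0.11, 0.0823, 0.0576 and 0.0932). Nfe2l1, a transcription factor gene the series title pairs with Sox9, was higher by 0.45 ± 0.08 at E13.5 and 0.52 ± 0.08 at E14.5. It stood at 0.16 ± 0.08 at the late age (adjusted p = 0.24). The Wnt antagonist Apcdd1 (1.10 ± 0.09, 1.29 ± 0.10, then 0.22 ± 0.09 with adjusted p = 0.17) and Zcchc24 (0.70 ± 0.09, 0.76 ± 0.10, then 0.18 ± 0.09 with adjusted p = 0.24) had the same course. Gfap and the water channel gene Aqp4 were higher at the late age, by 1.16 ± 0.14 and 0.92 ± 0.13. They did not pass before, at -0.12 ± 0.14 and 0.15 ± 0.13 at E13.5 and 0.13 ± 0.16 and 0.32 ± 0.15 at E14.5. At E13.5 Gfap lay at 7.01 to 7.22 in GFP cells and 7.17 to 7.29 in whole, under the array medians (7.73 to 7.80). Aqp4 lay at 7.29 to 7.85, near them. Early ratios of both genes may be compressed by background, which was not measured.

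Olig2, which specifies motor neurons and oligodendrocytes, was higher in GFP cells at E13.5 (0.58 ± 0.10) and lower at the late age (-0.50 ± 0.10; without the E18.5 arrays -0.43, adjusted p = 0.0521). Its value of 0.35 ± 0.12 at E14.5 (adjusted p = 0.047) did not pass with quantile normalization (0.29, adjusted p = 0.0861). It did not pass without either GFP array (adjusted p = 0.208 and 0.148) or without whole replicate 1 or 3 (0.11 and 0.155). Nfib stood at 0.35 ± 0.09 at E13.5 (adjusted p = 0.01, and 0.0527 without whole replicate 3), 0.12 ± 0.10 at E14.5 and 0.40 ± 0.09 at the late age (adjusted p = 0.0091, and 0.0529 without whole replicate 3). Fabp7, a radial glial fatty acid binding protein, did not pass at any age (0.15 ± 0.07, 0.16 ± 0.08 and 0.00 ± 0.07). Its log2 values lay at 13.40 to 13.73, near the highest of any gene, where differences can be compressed.

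**Figure D2:**
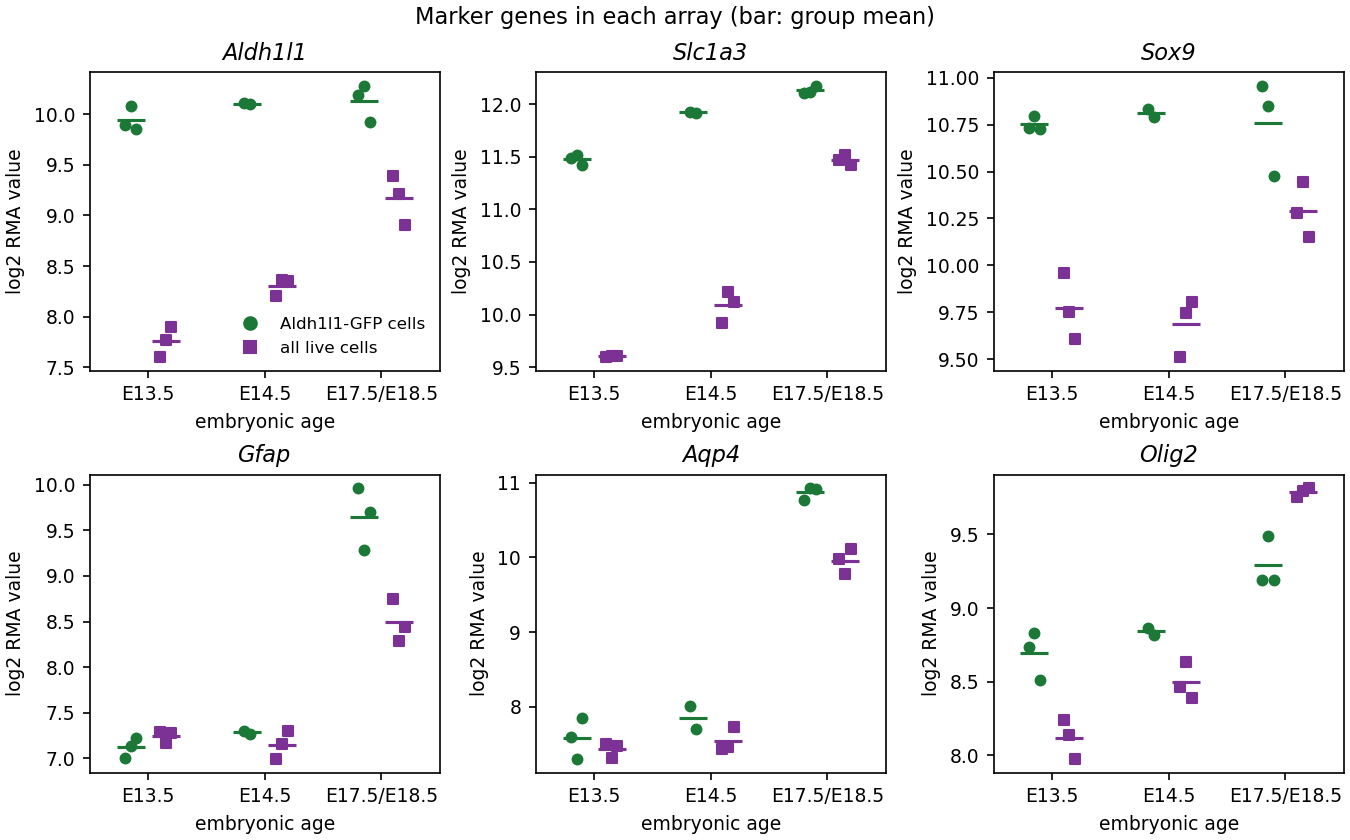
Deposited log2 values of Aldh1l1, Slc1a3, Sox9, Gfap, Aqp4 and Olig2 on each array by embryonic age, for GFP cells and all live cells; points are arrays and bars are group means. Aldh1l1 lay at 9.85 to 10.08 in GFP cells at E13.5 and 9.93 to 10.28 at the late age, while in all live cells it lay at 7.60 to 7.90 and then 8.91 to 9.39.

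Within the GFP cells, the change from E13.5 to the late age (n = 3 against 3) asks what accompanies the passage from radial glia to astrocytes. Astrocyte transcripts rose, and several neuronal transcription factors and other neuronal transcripts fell. The largest rises were Scrg1 (4.0 ± 0.19), Aqp4 (3.30 ± 0.13), the peptidase Folh1 (3.26 ± 0.25) and the cilium gene Cfap43 (3.22 ± 0.20). Luzp2 (3.08 ± 0.15), the apolipoprotein gene Apoe (2.98 ± 0.10) Tnc (2.84 ± 0.19) and Gfap (2.52 ± 0.14) also rose. The newborn neuron factors Neurod4 (-3.82 ± 0.18), Nhlh1 (-3.60 ± 0.16) and Neurod6 (-3.07 ± 0.21) and the dorsal progenitor factor Olig3 (-3.35 ± 0.21) were among the largest falls. Ebf1 (-2.87 ± 0.15), the neuronal tubulin Tubb3 (-2.77 ± 0.14) and the axon guidance receptor Dcc (-2.65 ± 0.14) fell too. Of 3870 genes past the threshold, 1740 were higher and 2130 lower late (45% higher, and 31.6% once each array was shifted to a common median). In the astrocyte list 29 of 30 rose (median 1.42; Cldn10 2.40 ± 0.12, Gja1 1.62 ± 0.09). In the ependymal and cilia list 12 of 16, rose, or 13 adjusted over the list alone (Mia 2.69 ± 0.13, Rsph4a 2.07 ± 0.18, Dynlrb2 1.57 ± 0.17).

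Pan-neuronal genes fell for 13 of 23 and rose for 1 between these ages (Elavl4 -2.65 ± 0.10, Dcx -2.30 ± 0.11). Proteasome subunits fell for 16 of 31, or 22 adjusted over the list alone (Psmc1 -0.55 ± 0.10, Psmc6 -0.50 ± 0.08; adjusted p = 4.81e-11, and 0.0493 with an estimated correlation). Dorsoventral patterning genes fell for 9 of 20 and rose for 2 (Dbx1 -1.25 ± 0.13, Reln 0.95 ± 0.09; adjusted p = 0.132 with an estimated correlation). Secreted and matrix proteins rose for 8 of 23 and fell for 4 (Bcan 1.47 ± 0.09; adjusted p = 0.278 with it). Radial glial genes went both ways, 3 higher and 5 lower of 20 (Nes -1.52 ± 0.11, Lipg -1.21 ± 0.10; adjusted p = 0.548 with an estimated correlation). That call ended with quantile normalization (0.219) and median shifting (0.0533). The oligodendrocyte lineage had 6 higher and 2 lower of 20 (Olig1 1.22 ± 0.11; adjusted p = 0.614 with an estimated correlation) and mitosis 2 lower of 24 (median -0.21; adjusted p = 0.614 with it). Immediate early genes had 2 higher of 19 (Ier3 and Zfp36, with adjusted p = 0.0589 and 0.0807 without GFP late replicate 1; adjusted p = 0.618 for the list with an estimated correlation). The mitosis and immediate early lists did not pass fry either (adjusted p = 0.149 and 0.216). Without the E18.5 arrays the oligodendrocyte and mitosis lists no longer passed camera (adjusted p = 0.116 and 0.143). Not passing were the gliogenic (2 higher, 1 lower), Notch (2 higher, 5 lower), DNA replication (5 lower) and spinal neuron identity (3 lower) lists. Nor did microglia (0), endothelial (2 higher), mural (3 higher), meningeal (1 higher, 1 lower), erythroid (1 higher), Schwann cell (0) and cholesterol synthesis genes (1 lower) pass, and adjusted p ran from 0.15 to 0.991. The spinal neuron median (0.02) had the opposite sign to its test. Adjusted over the list alone, the other counts differed by at most 2. Among the fixed genes Mmd2 (1.49 ± 0.09), Slc1a3 (0.66 ± 0.07), Olig2 (0.60 ± 0.10) and Zcchc24 (0.47 ± 0.09) rose, and Apcdd1 (-0.67 ± 0.09) and Nfib (-0.39 ± 0.09) fell. Aldh1l1 (0.19 ± 0.12, adjusted p = 0.32), Sox9 (0.01 ± 0.12), Nfia (0.08 ± 0.10), Fabp7 (0.07 ± 0.07) and Nfe2l1 (-0.22 ± 0.08, adjusted p = 0.055) did not pass. With median shifting Nfe2l1 did (-0.28, adjusted p = 0.0145).

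The step from E13.5 to E14.5 within the GFP cells (n = 2 against 3) brought more of astrocyte and sterol transcripts and less of mitotic ones. Tnc rose by 2.34 ± 0.22, Mia by 1.89 ± 0.14, the desaturase Scd1 by 1.35 ± 0.12, Car2 by 1.34 ± 0.17 and Apoe by 1.30 ± 0.11. Olig3 changed by -1.85 ± 0.23, Neurod4 by -1.63 ± 0.20 and the gap junction gene Gjb2 by -1.51 ± 0.22. Lower too were the mitotic cyclin Ccnb1 (-1.38 ± 0.20), the spindle gene Knstrn (-1.41 ± 0.20) and the homeobox factor Msx3 (-1.35 ± 0.17). In all 359 genes passed, 218 higher and 141 lower, 50 of them with a log2 change of at least 1. The mitosis list fell for 15 of 24 genes, or 22 adjusted over the list alone (median -0.77; Ndc80 -0.98 ± 0.14, Bub1 -0.93 ± 0.14; adjusted p = 1.53e-32, and 0.0139 with an estimated correlation). Astrocyte genes rose for 12 of 30, or 18 adjusted over the list alone (Slc4a4 1.18 ± 0.15, Slc7a10 0.90 ± 0.11). Cholesterol synthesis rose for 5 of 20, or 17 adjusted over the list alone, as a list (median 0.39; adjusted p = 3.09e-16, and 0.00313 with an estimated correlation). Only Hmgcs1, Fdps, Lss and Nsdhl among its members were named by the rule, and without GFP E14.5 replicate 2 their adjusted p rose to 0.282, 0.198, 0.217 and 0.159. Secreted and matrix proteins rose for 5 of 23 (Bcan 0.89 ± 0.10, Ncan 0.65 ± 0.10) and ependymal genes for 1 of 16, or 4 adjusted over the list alone (Mia, given above). Pan-neuronal genes fell for 3 of 23, or 5 adjusted over the list alone (Elavl4 -0.67 ± 0.11, adjusted p = 0.0593 without GFP E14.5 replicate 1).

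DNA replication (0 of 24, and 4 lower adjusted over the list alone; median -0.21) and proteasome subunits (0 of 31, and 2 lower; median -0.16) passed as lists between E13.5 and E14.5 without any single gene passing, with adjusted p = 0.17 and 0.0986 with an estimated correlation. So did the gliogenic factors (median 0.15, adjusted p = 0.359 with an estimated correlation) and immediate early genes (median 0.21, adjusted p = 0.725 with it). Of these lists only proteasome subunits passed fry (adjusted p = 0.0141). Fry gave 0.0739 for DNA replication, 0.187 for gliogenic factors and 0.636 for immediate early genes. The remaining lists did not pass camera: radial glia (1 higher, 1 lower), Notch (0), oligodendrocyte lineage (1 higher), spinal neuron identity (0), and dorsoventral patterning (1 higher, 3 lower). The same held for microglia (0), endothelial (0), mural (0), meningeal (0), erythroid (0) and Schwann cell genes (0), with adjusted p from 0.0614 to 0.76. The oligodendrocyte and spinal neuron medians (-0.01 and 0.01) had the opposite sign to their tests. Counts not given differed by at most 3 adjusted over the list alone. Of the fixed genes Mmd2 rose (0.82 ± 0.10), and Slc1a3 rose by 0.45 ± 0.08, a call that ended without either E14.5 array (adjusted p = 0.113 and 0.106). The count of genes depended on single arrays: it was 117 without GFP E14.5 replicate 1, 102 without replicate 2, 187 without GFP E13.5 replicate 1 and 210 without replicate 3. With 1 array left at E14.5, that array was assumed to vary like the other groups.

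From E14.5 to the late age (n = 3 against 2) the GFP cells gained astrocyte transcripts. Scrg1 rose by 3.46 ± 0.21, Aqp4 by 3.02 ± 0.15, the serine protease Htra1 by 2.74 ± 0.31, Selenom by 2.45 ± 0.15, Gfap by 2.36 ± 0.16 and Cldn10 by 2.22 ± 0.13. Among the falls were Nhlh1 (-2.82 ± 0.18), the calcium channel subunit Cacna2d1 (-2.64 ± 0.30), Adamts3 (-2.23 ± 0.40) and Tubb3 (-1.99 ± 0.16). Of 1486 genes past the threshold 704 were higher and 782 lower late (47.4% higher, and 33.8% with median shifting), 214 with a log2 change of at least 1. Astrocyte genes rose for 24 of 30, or 26 adjusted over the list alone, and ependymal genes for 8 of 16, or 11 adjusted over the list alone (Rsph4a 1.41 ± 0.20). Cholesterol synthesis fell for 9 of 20, or 16 adjusted over the list alone (Hmgcs1 -0.59 ± 0.08; adjusted p = 3.03e-13, and 0.00354 with an estimated correlation). Pan-neuronal genes fell for 6 of 23 (Elavl4 -1.98 ± 0.11). Mitosis rose for 10 of 24, or 18 adjusted over the list alone (median 0.57; adjusted p = 0.18 with an estimated correlation). Both E14.5 comparisons within GFP cells use the same 2 arrays, so chance values of those arrays enter them with opposite signs.

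In camera, other lists passed from E14.5 to the late age with the preset correlation but not with an estimated one. Dorsoventral patterning (3 lower, Dbx1 -1.21 ± 0.14, adjusted p = 0.18 with an estimated correlation) and radial glia (4 lower, Lipg -1.26 ± 0.11, Nes -0.92 ± 0.13, adjusted p = 0.234 with it) did so. The oligodendrocyte lineage (5 higher, Olig1 0.84 ± 0.13, adjusted p = 0.523 with an estimated correlation) and proteasome subunits (1 lower, adjusted p = 0.234 with it) did so too. Of these lists only the oligodendrocyte lineage did not pass fry (adjusted p = 0.0903). Gliogenic (1 lower), Notch (2 lower), DNA replication (0), spinal neuron identity (2 lower), microglia (1 higher) and endothelial genes (2 higher) did not pass as lists. Nor did mural (1 higher, 1 lower), meningeal (1 higher, 1 lower), erythroid (1 higher), Schwann cell (1 lower), immediate early (0) and secreted protein genes (6 higher, 3 lower), with adjusted p from 0.126 to 0.8. The Schwann cell median (0.07) had the opposite sign to its test. Adjusted over the list alone, the other counts differed by at most 2. Apcdd1 fell (-0.64 ± 0.10) and Mmd2 rose (0.67 ± 0.10), while Sox9 (-0.05 ± 0.14) and Nfia (-0.06 ± 0.11) did not pass. Without GFP E14.5 replicate 1 the count was 670 and without replicate 2 it was 660; with only these 2 groups in the fit it was 545.

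**Figure D3:**
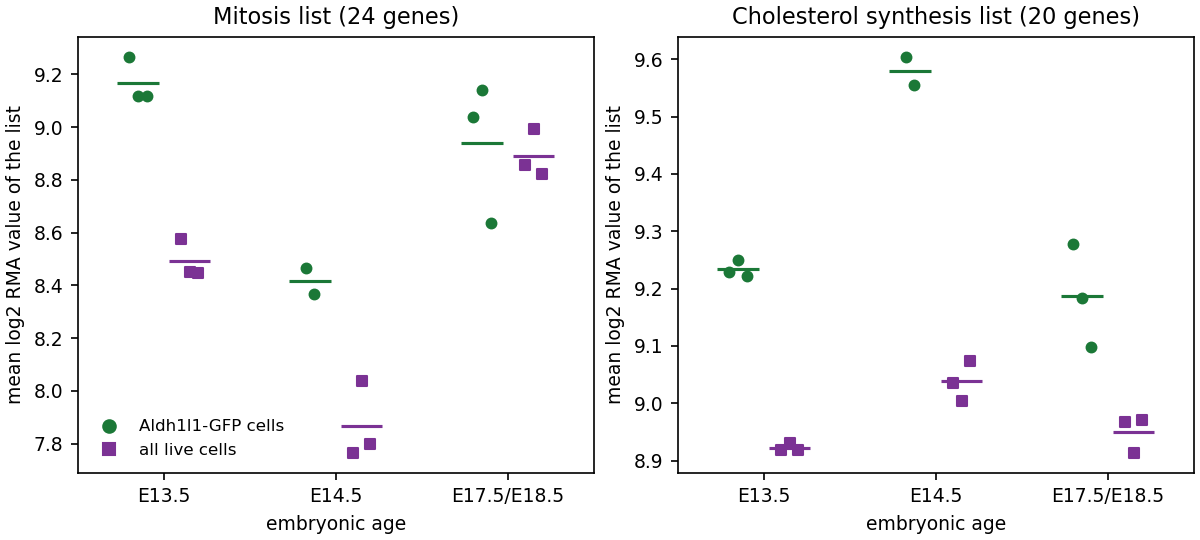
Mean log2 value over the 24 mitosis genes and over the 20 cholesterol synthesis genes on each array, by embryonic age; points are arrays and bars are group means. For mitosis the GFP arrays at E14.5 lay at 8.47 and 8.37, under the lowest GFP array of the other ages (8.64); for cholesterol synthesis they lay at 9.60 and 9.56, over the highest of the others (9.28).

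In all live cells the change from E13.5 to the late age (n = 3 against 3) gives the background against which the GFP cells moved. Glial, immune and vascular transcripts rose and neuronal and embryonic globin transcripts fell. Scrg1 rose by 3.97 ± 0.19, Mia by 3.74 ± 0.13, Slc4a4 by 3.73 ± 0.13, Tnc by 3.67 ± 0.19, Slc6a11 by 3.31 ± 0.18 and Aldh1l1 by 1.42 ± 0.12. Hbb-y (-5.91 ± 0.27), Neurod6 (-3.57 ± 0.21), the dorsal interneuron factor Tfap2b (-3.40 ± 0.23), Nhlh1 (-3.23 ± 0.16) and Ebf2 (-2.84 ± 0.09) were among the largest falls. Of 4816 genes past the threshold 2434 were higher and 2382 lower, 505 and 212 of them by a log2 of at least 1. Astrocyte genes rose for 27 of 30 (Sparcl1 2.04 ± 0.07), oligodendrocyte lineage genes for 16 of 20 (Pdgfra 2.81 ± 0.14, Gpr17 1.83 ± 0.13). Microglia genes rose for 16 of 18 with 1 lower (Ly86 2.41 ± 0.11, Ctss 2.16 ± 0.13) and endothelial genes for 13 of 18 (Kdr 1.16 ± 0.10). Mural genes rose for 9 of 14 (Higd1b 1.93 ± 0.11), ependymal genes for 12 of 16 (Dnah6 2.53 ± 0.19) and secreted and matrix proteins for 11 of 23 (Timp4 3.14 ± 0.19). Pan-neuronal genes fell for 18 of 23 (Ina -2.13 ± 0.15) and spinal neuron identity genes for 11 of 23 (Slc17a6 -2.54 ± 0.14). Adjusted over the list alone these counts differed by at most 3. The rises and falls shared with the GFP cells numbered 963 and 1090, where independent lists would share 178 and 213. Whole holds the GFP cells, so a change in them enters whole as well. The numbers for independent lists therefore do not test this overlap.

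In all live cells, gliogenic factors rose for 9 of 19 and fell for 1 (Tcf7l2 1.42 ± 0.12; adjusted p = 0.0555 with an estimated correlation). Mitosis genes rose for 10 of 24 (Mki67 0.76 ± 0.13; adjusted p = 0.182 with an estimated correlation). Notch genes rose for 5 with 1 lower of 18 (Hey2 1.54 ± 0.15; adjusted p = 0.211 with an estimated correlation) and immediate early genes for 4 of 19 (Jun 0.91 ± 0.18; adjusted p = 0.382 with it). The immediate early list did not pass fry either (adjusted p = 0.0989). Meningeal genes fell for 7 of 16 (Lum -1.63 ± 0.18; adjusted p = 0.0541 with an estimated correlation) and proteasome subunits for 10 of 31 (Psmd14 -0.61 ± 0.09; adjusted p = 0.106 with it). Erythroid genes fell for 3 of 14 (adjusted p = 0.182 with an estimated correlation), and radial glial genes went both ways, 4 higher and 4 lower of 20 (Ptprz1 2.20 ± 0.12; adjusted p = 0.192 with it). DNA replication (3 higher, 1 lower), dorsoventral patterning (2 higher, 6 lower), Schwann cell (1 higher, 3 lower) and cholesterol synthesis genes (1 higher, 2 lower) did not pass as lists (adjusted p from 0.106 to 0.436). Counts adjusted over the list alone differed by at most 4.

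The interaction tests whether the change with age differed between GFP cells and all live cells, or equally whether the GFP to whole ratio changed from E13.5 to the late age. It passed for 1095 genes, 382 with a more positive change in GFP cells and 713 with a more negative one. The ratio of Aldh1l1 shrank by an interaction of -1.22 ± 0.17 and that of Slc1a3 by -1.21 ± 0.11, because both rose more in all live cells. That of Gfap grew by 1.28 ± 0.20, from values under the array medians at E13.5, where a ratio may be compressed. Pdgfra (-2.41 ± 0.21), Adamts3 (-2.32 ± 0.50), the cadherin Pcdh15 (-2.43 ± 0.19) and Ly86 (-2.55 ± 0.16) were among the most negative. Hbb-y (6.0 ± 0.39), Runx1t1 (2.25 ± 0.15), Mab21l2 (2.23 ± 0.16) and the neuropeptide gene Npy (2.04 ± 0.25) were among the most positive. Lists with a more negative change in GFP cells were microglia (13 of 18; median -1.14), mitosis (10 of 24, or 17 adjusted over the list alone; Kif11 -1.12 ± 0.22) and oligodendrocyte lineage (9 of 20; Gpr17 -1.87 ± 0.18). Endothelial (7 of 18; Slco1c1 -1.99 ± 0.17) and radial glial genes (6 of 20, or 12 adjusted over the list alone; Ptprz1 -1.38 ± 0.18) also changed more negatively. The rest were mural (3 of 14; Higd1b -2.01 ± 0.16), secreted and matrix proteins (8 of 23; Timp3 -1.25 ± 0.17) and Notch (2 of 18, or 6 adjusted over the list alone; Hey1 -0.62 ± 0.14). Spinal neuron identity (8 of 23; Isl1 1.39 ± 0.16, Lhx1 1.37 ± 0.14) and meningeal genes (6 of 16; Postn 1.64 ± 0.18) had a more positive change. These directions are relative to all live cells. Within GFP cells 0 microglia genes passed with age (median 0.11), while 16 rose and 1 fell in all live cells (median 1.24). Endothelial genes rose for 2 in GFP cells and 13 in all live cells, with 0 lower in either. Of spinal neuron identity genes 3 fell and 0 rose in GFP cells, against 11 and 0 in all live cells. In all live cells Hbb-y fell by -5.91 ± 0.27.

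Further lists passed the interaction in camera with the preset correlation but not with an estimated one. They were astrocyte genes (5 higher, 11 lower of 30; Aldoc -1.65 ± 0.18; adjusted p = 0.152 with an estimated correlation) and gliogenic factors (5 lower; Tcf7l2 -1.18 ± 0.17; adjusted p = 0.0544 with it). DNA replication (1 lower; adjusted p = 0.268 with an estimated correlation) and dorsoventral patterning (1 higher, 2 lower; Nkx2-2 -1.34 ± 0.16; adjusted p = 0.178 with it) were others. The last were ependymal genes (2 lower, Mia -1.05 ± 0.18, adjusted p = 0.0703 with an estimated correlation) and erythroid genes (3 higher, Hbb-bh1 3.00 ± 0.25, adjusted p = 0.068 with it). Of these lists DNA replication and dorsoventral patterning did not pass fry (adjusted p = 0.23 and 0.0641), and the others did. Pan-neuronal (4 higher, 3 lower; adjusted p = 0.26), Schwann cell (0; 0.0768), immediate early (0; 0.296), cholesterol synthesis (0; 0.107) and proteasome genes (0; 0.0936) did not pass. The immediate early median (0.07) had the opposite sign to its test. Adjusted over the list alone, the counts not given differed by at most 5. Of the fixed genes, Olig2 (-1.08 ± 0.15), Apcdd1 (-0.88 ± 0.13), Zcchc24 (-0.52 ± 0.12), Nfia (-0.54 ± 0.14) and Aqp4 (0.76 ± 0.19) passed. Sox9 (-0.51 ± 0.17, adjusted p = 0.12), Nfe2l1 (-0.29 ± 0.11, 0.14), Nfib (0.04 ± 0.13), Fabp7 (-0.14 ± 0.10) and Mmd2 (-0.13 ± 0.13) did not. The calls of Nfia (adjusted p = 0.034) and Aqp4 (adjusted p = 0.026) each ended without any 1 of several arrays. Without GFP E13.5 replicate 2, for example, adjusted p was 0.0828 for Nfia and 0.0681 for Aqp4. That of Zcchc24 ended without the E18.5 arrays (0.0713) and without GFP E13.5 replicate 2 (0.0623) or whole E13.5 replicate 2 or 3 (0.0573 and 0.0528), and that of Aqp4 also with quantile normalization (0.0808).

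The study's deposited coexpression modules were counted in the same fit. They were built on these same 17 arrays, so their directions are not independent evidence. In the red module, labelled early (79 genes, led by Gask1b, Ptpn13 and Sfrp2), all 79 genes were higher in GFP cells at E13.5 and E14.5 and 27 at the late age. In GFP cells 69 of them fell from E13.5 to the late age. In the turquoise module, labelled middle (328 genes, led by Ttyh1, Ednrb, Abcd3 and Eif2ak2), 328, 328 and 220 genes were higher in GFP cells at the successive ages. In the yellow module, labelled late (164 genes, led by Slc4a4, Ramp1, Arap2 and Ahcyl1), all 164 rose with age both in GFP cells and in all live cells. In the pink module, labelled mitosis (48 genes, led by Cdk1, Kif4, Aspm and Smc2), 46, 34 and 0 genes were higher in GFP cells at the successive ages, and 26 fell within GFP cells from E13.5 to E14.5.

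The authors' deposited table for E13.5 listed 1875 genes, 1173 higher in GFP cells, and 1648 of them had an adjusted p under 0.05 there. Of the 1849 with a gene used here, all 1849 had the same direction and 1811 passed. The authors' deposited table for the late age listed 683 genes, 436 with an adjusted p under 0.05. Of 674 with a gene used here, 673 had the same direction and 651 passed. In the authors' deposited table for E14.5, 0 of 552 genes had an adjusted p under 0.05 (the largest was 0.15). None of its 552 folds equalled the fold from the assigned arrays within 1e-04 on the log2 scale (median difference 0.444), and all 552 did once the array called mislabeled was counted among the GFP arrays. All 1875 folds of the E13.5 table and all 674 folds compared from the late table equalled those of the assigned arrays, and 0 of the 674 did without the E18.5 arrays. For Aldh1l1 at E13.5 the authors' deposited table gave a fold of 4.55 with an adjusted p of 0.0106, and for Gfap at the late age 2.23.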

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

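Of the tests below, the microglia median, both tests of newborn neurons and the test on all live cells at E14.5 were chosen only after the result was seen, and the others before. The medians over the brightest members of lists had no prediction written for them and are description only.

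What follows differed between E13.5 and the late age in a limma test of the difference of the GFP to whole ratios (interaction, log2, late minus E13.5, with 3 arrays in each of 4 groups). Among genes of astrocytes and progenitors the values were Aldh1l1 -1.22, Slc1a3 -1.21, Adamts3 -2.32, Sparcl1 -1.34, Timp3 -1.25, Mia -1.05, Id3 -0.91, Apcdd1 -0.88, Ednrb -0.87, Hey1 -0.62, Bcan -0.57, Sox2 -0.57, Nfia -0.54, Zcchc24 -0.52, Olig3 -1.13, Gfap 1.28 and Aqp4 0.76. Among oligodendrocyte lineage genes and Pcdh15 they were Pdgfra -2.41, Pcdh15 -2.43, Nkx2-2 -1.34 and Olig2 -1.08. Among microglial and other immune genes they were Ly86 -2.55, Hpgds -2.51, Il1a -2.46, Fcrls -2.41, Ctss -1.97, Tyrobp -1.70 and Aif1 -1.55, and among vascular genes Ctla2a -3.22, Slco1c1 -1.99 and Abcc9 -1.30. Embryonic globins gave Hbb-y 6.0, Hbb-bh1 3.00 and Hba-x 2.90. Neuronal and remaining genes gave Slc7a11 2.28, Runx1t1 2.25, Mab21l2 2.23, Mgat4c 2.06, Npy 2.04, Postn 1.64, Gad2 1.07, Elavl4 -0.85 and Dcx -0.74. The list medians that differed were microglia -1.14, mitosis -0.70, radial glia -0.53, oligodendrocyte lineage -0.48, endothelial -0.47, mural -0.46, Notch -0.31, secreted and matrix proteins -0.21, spinal neuron identity 0.33 and meningeal fibroblast 0.31. Sparcl1 had late means of 13.59 and 13.77, near the highest of any gene, where differences can be compressed. Gfap lay under the array medians at E13.5, where differences can be compressed too.

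Several astrocyte genes with large GFP to whole ratios at E13.5, such as Aldh1l1 and Slc1a3, had smaller ones at the late age. If GFP cells made up a larger share of all live cells late, such ratios would shrink together and stay positive. Of the 18 genes with a log2 ratio of at least 2 at E13.5, 88.89% kept a late ratio above 0.3, so a larger share may account for part of the pattern; these genes were picked by their E13.5 ratio, which by itself favours a smaller late one. Other genes did not shrink with them: Mmd2 went from 1.13 to 1.00 (interaction -0.13, adjusted p = 0.62), and the astrocyte list had 5 genes with a more positive and 11 with a more negative change (adjusted p = 0.152 with an estimated correlation). Mmd2 also rose within GFP cells (1.49). Gfap and Aqp4, among those with a more positive change, lay under or near the array medians at E13.5. These genes therefore do not decide whether the share grew. Other cells of all types alike carried into the late GFP sort would instead keep the transcripts of every type near the level of all live cells, but the microglia median stood at -1.65, which argues against it. The late medians of other lists were nearer that level (endothelial -0.58, oligodendrocyte lineage -0.51, mural -0.45, spinal neuron identity -0.06, meningeal fibroblast -0.05). Over the 5 members of each list brightest in whole, the late medians were -1.11, -1.68, -2.16, -0.58 and -0.04 in the same order. The first 3 of these lists stood well below all live cells in their brightest members, and the meningeal list did not. These members were picked by their level in whole, the denominator of the ratio, which by itself favours a lower ratio. Their medians therefore do not decide whether such cells were carried over. Carry-over of single cell types was not excluded. A growing astrocyte population is the biological form of the larger share; a change of regulation in single genes was not tested apart from it.

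Transcripts of newborn neurons were measured in the GFP cells at E13.5 and were lower there at the late age. At E13.5, 10 of 12 were lower than in all live cells (Neurod6 -1.86, median -0.91), 1 was higher (Neurod4 1.21) and Nhlh1 (0.08) did not pass. Neurons of all stages carried into the sort would give newborn and mature transcripts the same ratio, and newborn neurons that still hold GFP from their progenitors would give the newborn ones a higher ratio. The newborn median exceeded the mature one by 0.47 (12 against 20 genes, permutation p = 0.146). Of the mature genes 16, and of the newborn genes 4, were also in the gene lists above, whose results were already known. The permutation and the bootstrap below ran over genes that can move together, so neither measures the spread between arrays. That all 12 newborn transcripts fell from E13.5 to the late age restates the pattern and decides nothing. By the rule first written the difference counted as carried-over neurons; after that outcome was seen a bootstrap interval over genes was added, which ran from -0.138 to 1.10, and the question was left open, so either source could be at work. Of 10 neurogenic progenitor genes 1 was higher and 1 lower than in all live cells at E13.5 (median 0.06). In GFP cells 7 of the 10 fell from E13.5 to the late age (median -0.42). An end of neurogenesis by the late age was not tested apart from either source.

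Mitotic transcripts in the GFP cells were lower at E14.5 than at E13.5. They were also lower than at the late age with the preset correlation and with fry (adjusted p = 0.00817). With an estimated correlation that call was lost (adjusted p = 0.18), and 10 of 24 genes passed singly. With 1 low array alone, the other E14.5 array would lie among those of the other ages, but both lay below all of them, with a gap of 0.172 in log2, which argues against it; the nearest was the E18.5 array (8.64 against 8.47). A difference shared by all cells collected at E14.5 would also appear in all live cells, where the mitosis list changed by a median of -0.61 from E13.5 to E14.5 with 10 of 24 genes lower, so it may be shared. Whole holds the GFP cells, so a fall in them alone would also lower whole to some degree. Age and collection go together here, so a fall of division in the cord at E14.5 and a difference of handling were not separated.

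Labels were also exchanged between groups. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Every other split also mixes the real groups, which carries their difference into the spread within groups and lowers the count. The counts of these splits therefore do not show whether chance can be excluded. For GFP against whole at E13.5 the real split gave 4557 genes and no other any, so 1 split, the real one, reached that number; at the late age it was 2214 against at most 9 (1 split), for GFP late against E13.5 3870 against 0 (1 split), and for whole late against E13.5 4816 against 0 (1 split). For the interaction, 3 of 100 draws of the 12 arrays into 4 groups, the real one included, gave at least 1095 genes, and the highest other gave 2321. Draws that mix sort with age carry those differences into the spread within groups or into the contrast, so this share does not show whether chance can be excluded for the interaction.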

How the results depend on the processing

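No test in this part was chosen after the result was seen. No called gene, list or module turned its direction under any alternative (direction was examined for called results only). The balance of higher and lower genes did turn where it was near even: for GFP against whole at the late age from 49.6% higher to 58.1% without dim genes and 53.3% without E18.5, for whole late against E13.5 from 50.5% to 45.4% with median shifting, and for GFP late against E14.5 from 47.4% to 54.1% with only its groups in the fit. With a log2 change of at least 1, GFP late against E13.5 went from 45% to 61.4%. With array weights GFP E14.5 against E13.5 gave 833 genes, among them all 359; the cause was not tested. With only the groups of a comparison in the fit, GFP against whole at the late age gave 1020 and GFP late against E14.5 gave 545. Fewer arrays do not account for this alone, since GFP against whole at E13.5 rose to 5476 and GFP E14.5 against E13.5 to 522. The residual spread of the late arrays was 0.135 to 0.169, against 0.105 to 0.115 at E13.5. The joint fit gives all groups the same spread per gene, so it may understate errors at the late age. A log2 change of at least 1 left, by construction, 589, 882 and 308 genes for GFP against whole at E13.5, E14.5 and the late age, 435 for GFP late against E13.5, 50 for E14.5 against E13.5, 214 for late against E14.5, 717 for whole late against E13.5 and 288 for the interaction. Leaving out each array in turn gave 102 to 248 for GFP E14.5 against E13.5 and 660 to 1355 for late against E14.5, with fewer arrays; the other counts stayed within 1.5 times, at 3457 to 3897, 2947 to 4197 and 1638 to 2394 for GFP against whole at the successive ages, 2749 to 3610 for GFP late against E13.5, 3855 to 4423 for whole and 780 to 1151 for the interaction. Where a single array was left in a group, it was assumed to vary like the other groups. Without both E18.5 arrays the late comparison gave 1915. Of the named genes (770 results), other settings kept 10961 values on their side of the threshold, took 534 below it and brought 31 past it; for lists (168 results) these were 850, 77 (47 of them with an estimated correlation) and 18, and for modules (32 results) 169, 6 and 5. Leaving out E18.5 also brought DNA replication (0.00724) and immediate early genes (0.0162) past the threshold in GFP cells from E14.5 to the late age, and pan-neuronal genes (0.0458) in the interaction. With the replicate number as a block the counts were 4029, 3421 and 1882 for GFP against whole, 3865, 354 and 1500 within GFP cells, 4811 for whole and 928 for the interaction; deviations of arrays with the same number correlated at -0.081 to 0.121 and 4 of 16 arrays correlated best with their own number, so the numbers were not taken as pairs. No detection p was used, so signal over background was not measured, and dim genes were limited only through the filter at the 40th percentile, which moved no count by over 1.5 times.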

Other observations

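No test in this part was chosen after the result was seen, because none was run. Ciliary and ependymal transcripts rose with age in both sorts: Rsph4a, a radial spoke gene of motile cilia, by 2.07 ± 0.18 in GFP cells and 2.62 ± 0.18 in all live cells from E13.5 to the late age, and Cfap43 by 3.22 ± 0.20 and 3.41 ± 0.20. Reln, which encodes a guidance glycoprotein, rose in GFP cells by 0.91 ± 0.10 from E13.5 to E14.5, while the progenitor factors Dbx1, Neurog2 and Olig3 fell by the late age (-1.25 ± 0.13, -0.93 ± 0.10 and -3.35 ± 0.21).

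The array whose title calls it mislabeled was put in no group and entered no comparison. Its log2 values were 7.13 for Aldh1l1, 9.10 for Sox9, 7.33 for Gfap and 8.88 for Slc1a3. Over all genes it correlated at 0.988 to 0.992 with whole at E14.5, 0.986 to 0.989 with whole at E13.5, 0.955 to 0.960 with whole at the late age, 0.950 to 0.952 with GFP cells at E14.5, 0.954 to 0.955 with GFP cells at E13.5 and 0.932 to 0.934 with GFP cells at the late age. The authors' deposited E14.5 folds equal those computed with this array among the GFP arrays for 552 of 552 genes. The deposited list of the pink module holds 48 genes and the deposited module statistics give it 45.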
